A study of Mus musculus with 3 samples.

How the data were processed

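Genomic DNA of the mouse bladder cancer cell line MB49 was sequenced after exome capture, with paired-end Illumina reads per the labels. There were 3 libraries, from the parental line, a derived line labelled Y chromosome positive and a derived line labelled Y chromosome negative. Each group held 1 library. No test across samples was therefore possible, and every Fisher exact test compared the reads or entries of 2 libraries, not the conditions. Groups followed the genotype and title of each sample. The sample descriptions MBN, on the Y positive sample, and MBP, on the Y negative sample, run against those labels if N and P stand for negative and positive, which no label states.

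The submitters' processing notes name BWA, a read aligner, and Picard, a toolkit for read files, without versions. They also name the genome builds mm9 and mm10. The deposited files reach position 197068016 on chromosome 1 and 152408092 on chromosome 7, while the last genes of the GRCm38 (mm10) gene table end at 195291439 and 145324059. The coordinates are therefore not those of mm10, and mm9 is the only other build the notes name. The variant caller and its version are not given in the sources used here.

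Each deposited file listed 1 library's variants with their place relative to gene models and their predicted coding effect. All 11709 parental, 10334 Y positive and 12465 Y negative entries were insertions or deletions (indels), and all carried the filter value PASS. Substitutions were not analysed here. The authors' read counts per entry were whole numbers: the depth, and the reads carrying the reference and each alternative allele. The authors' quality score of each entry was phred-scaled and was not used as a filter here. The deposited genotype was homozygous, heterozygous for 1 alternative allele, or held 2 alternative alleles. A variant that a file does not list has no reference reads there, so absence from a list is not a measured reference genotype. It can also come from low depth or from the authors' caller and filters.

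The files gave Ensembl transcript identifiers and no gene symbols. Of the 21975 identifiers, 0 matched the RefSeq gene table used for names, which holds no Ensembl identifiers. Indels were therefore reported by position, with the first transcript identifier for a few of them. The gene lists fixed before the data were examined (Y-linked genes, their X homologues, pseudoautosomal genes, bladder cancer genes, antigen presentation, DNA repair, chromosome segregation, chromatin modifiers, long genes and chemosensory receptors) could not be applied, and no result is given for them. The rule for named genes asked for the members of these lists, the genes with most private protein-altering variants in each derived line, the largest allele fraction differences in protein-altering variants and the genes at the extremes of coverage. Without symbols it was applied to transcript identifiers and to windows of the genome. Indels singled out by position beyond that rule were chosen after their values were seen.

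Entries were matched between libraries on chromosome, position, reference and alternative allele. Sharing was given as the Jaccard index, the number of indels in both lists over the number in either. It was also computed over indels with a depth of at least 20 reads in at least 1 library. Shares carry exact (Clopper-Pearson) 95% intervals. Reads come without molecular identifiers, and neighbouring indels can lie on the same reads, so intervals and tests cover counting error only. Shares of entries were compared by Fisher exact tests, two-sided, in 1 family of 27 tests with Benjamini-Hochberg adjustment. Entries at depth 20 or more were also compared for each of 21 chromosomes between the Y negative and Y positive libraries, adjusted over those tests.

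Allele fraction, the reads with the alternative allele over all reads of the entry, was compared at indels with 1 alternative allele listed in both libraries at a depth of at least 20. A Fisher exact test, two-sided, of reference and alternative reads was run per site, with Benjamini-Hochberg adjustment per pair of libraries and a threshold of 0.05. Such a site had to be listed in both libraries, so a gain or loss that removed the entry from a list was not tested. Depth ratios were computed at the 4088 indels listed in all 3 libraries with 1 alternative allele at the site in each, as log2 of the depths after adding 0.5 reads, centred on the autosomal median. Medians were taken per chromosome and per 10 Mb window with at least 5 indels, against a limit of 0.5. Their intervals came from 2000 bootstrap draws of sites. These depths are those of called indels, not of all captured bases. An indel had to be listed in all 3 libraries, so a loss of depth that removed it from a list was not measured.

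Both steps were tested on simulated data. In the comparison of Y negative with Y positive over 2645 sites, 23 of 100 sites changed by 0.2 in allele fraction were recovered, 79 of 100 changed by 0.4 were recovered, and 0 unchanged sites were called. Over 2745 sites of Y positive against parental the counts were 25, 82 and 3, and over 2651 sites of Y negative against parental 31, 86 and 3. A chromosome 19 simulated at 0.5 of its depth in the Y negative library, over 4088 sites, came back at a log2 ratio of -1.05. In that simulation 2 of 203 windows on the other chromosomes passed the limit by counting noise. It drew counting noise alone around the mean depth of sites listed in all 3 libraries, so the recovered ratio was largely set by the input. Neither the wider scatter of real sites nor the loss of entries from a list at lower depth was simulated.

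The groups, tests, thresholds and most alternatives were fixed before the data were examined. The window sizes, the minimum of 5 indels per window, the limits of the far end of chromosome X, the listing of private coding indels at an allele fraction of at least 0.25, the comparison with autosomal sites of like depth and the windows of homozygous indels were chosen after seeing the data. Alternatives covered the depth and allele fraction minimums, the matching rule, the centring and the limit on depth ratios. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.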

Results

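MB49 is a mouse bladder cancer cell line, and the study set a derivative that keeps the Y chromosome beside a derivative that has lost it. The exome libraries of the parental line, the Y positive line and the Y negative line listed 11709, 10334 and 12465 indels. The median depth per listed indel was 9 reads in the parental library, 13 in Y positive and 7 in Y negative. Depth summed over entries was 322980, 317111 and 329187 reads in the same order. Each line was represented by 1 library, so no difference has a replicate check.

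The first question was whether the lists carry the Y chromosome difference that the labels name. Indels on chromosome Y were listed 9 times in the Y positive library, 4 times in the parental library and 0 times in the Y negative library. All lay in introns or between genes. In Y positive, 6 of the 9 had a depth of at least 20 reads, while the 4 parental entries had a median depth of 4.5 reads. In Y positive they included a single-base T deletion at Y:701278, carried by 26 of 26 reads, and a 6-base deletion at Y:2396558 to 2396563, carried by 21 of 45 reads. Every Y positive entry on Y except Y:701278 was deposited as heterozygous, and the reason was not tested. A single-base C deletion listed at Y:2396563 overlapped the 6-base deletion, so the 9 entries are not all separate places. The counts of Y entries went with the genotype labels and against a reading of the sample descriptions MBN and MBP as negative and positive.

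The share of Y entries differed between Y negative and Y positive (0 of 12465 against 9 of 10334, Fisher exact p = 0.000806, adjusted p = 0.00218). It did not pass the Fisher exact test between Y positive and parental (adjusted p = 0.283) or between Y negative and parental (adjusted p = 0.106). At depth 20 or more, over 21 chromosomes, Y had the smallest p in the comparison of Y negative with Y positive (0 entries against 6, Fisher exact p = 0.0313). That exact test did not pass adjustment (adjusted p = 0.657), and outside Y the smallest p was 0.131, on chromosome 14.

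Chromosome Y was also read less deeply in the parental library than in Y positive at the 2 sites listed in both. At Y:701278 the parental depth was 5 reads against 26, and at Y:2391149 it was 13 against 36. Together these were 18 parental and 62 Y positive reads, a ratio 0.283 times that of the 4893 autosomal indels listed in both libraries (Fisher exact p = 4.32e-07). Among autosomal sites within 25% of the same Y positive depth, 0 of 905 had a log2 ratio as low as Y:701278 and 3 of 905 as low as Y:2391149. The test rests on 2 sites, and their comparison with autosomal sites was chosen after the depths were seen.

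The mouse pseudoautosomal region, which X and Y share, lies towards the far end of chromosome X, but its border in these coordinates was not looked up here, so it is not known which of the indels below lie inside it. The 16 most distal X indels listed in all 3 libraries, a limit set after the depths were seen, from X:166414678 to X:166443332, had a median log2 depth ratio of -0.56 in Y negative over Y positive (95% interval -1.80 to -0.08). Depth was lower in Y negative at 12 of the 16. The median was 0.56 in Y positive over parental (0.18 to 1.31) and -0.25 in Y negative over parental (-0.54 to 0.12). Only 2 of the 16, both in the first cluster described below, had a depth of at least 20 in every library, and over these 2 the first median was -1.09 and the second 0.86. The other 84 X indels had medians of -0.04, 0.06 and 0.03 in the same order of comparisons.

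The 16 indels fell into 2 clusters that differed in depth ratio. The first held 9 indels in the exons and introns of non-coding RNA, from X:166414678 to X:166421683. Its summed depth was 801 reads in Y positive, 346 in parental and 270 in Y negative, and depth was lower in Y negative than in Y positive at 8 of the 9. The second held 7 intronic indels from X:166443210 to X:166443332, with 118, 121 and 111 reads. Within a cluster many indels can share the same reads, so the number of independent measurements is well below 16.

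At indels listed in all 3 libraries, autosomal depth differed little between the libraries. The median log2 ratio of Y negative over Y positive ranged from -0.13, on chromosome 7 (95% interval -0.18 to -0.04), to 0.05 over the 19 autosomes and X. For Y positive over parental the range was -0.16, on chromosome 17 (-0.23 to -0.10), to 0.15, and for Y negative over parental -0.07 to 0.06. Of 209 windows of 10 Mb, 3 passed an absolute log2 ratio of 0.5 between Y negative and Y positive, on chromosome 5 from 70000001 to 80000000 (0.79, 10 indels), on X from 50000001 to 60000000 (0.57, 7 indels) and on X from 90000001 to 100000000 (-0.63, 5 indels). Shuffling the ratios over sites gave 3 or more such windows in 41 of 100 draws, so the count was not above chance. With a depth of at least 20 in every library, 0 windows passed in any of the 3 comparisons. That minimum also removes indels, and windows left with fewer than 5 drop out, so this 0 does not retest all 209 windows.

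**Figure D1:**
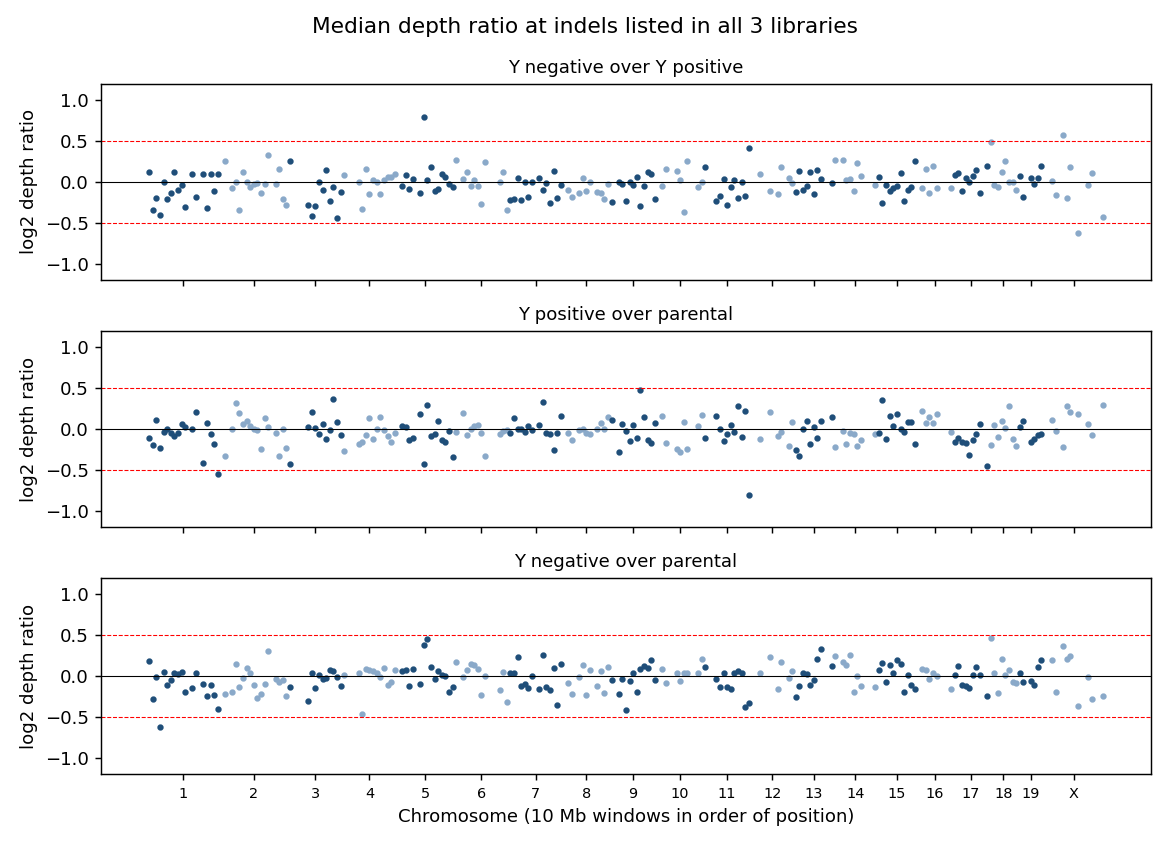
Median log2 depth ratio per 10 Mb window at indels listed in all 3 libraries, by chromosome and position, for each pair of libraries, with dashed lines at 0.5 and -0.5. Nearly all points lie between the dashed lines, with 3, 2 and 1 of 209 windows outside them from the upper to the lower panel.

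The next question was what kinds of indel each line listed. The Y negative library held more intergenic and more homozygous entries than Y positive, and the difference lay at low depth. Intergenic indels were 27.0% of Y negative entries (95% interval 26.2 to 27.8), 23.9% of parental entries and 18.0% of Y positive entries. Homozygous indels were 58.8%, 56.7% and 50.3% in the same order. Entries below 5 reads were 44.1% in Y negative, 39.7% in parental and 30.2% in Y positive.

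Between Y negative and Y positive all 3 shares differed by Fisher exact tests (adjusted p = 1.02e-57 for intergenic, 7.47e-37 for homozygous and 5.30e-102 for low depth). At depth 20 or more, where the libraries listed 4044 indels in Y negative, 4086 in parental and 4155 in Y positive, by Fisher exact tests neither the intergenic share (289 of 4044 against 287 of 4155, adjusted p = 0.819) nor the homozygous share (26.1% against 27.4%, adjusted p = 0.283) passed the test. Deletions were 75.3% of parental, 75.9% of Y positive and 75.7% of Y negative indels at that depth. Single-base A or T indels were 45.8%, 47.1% and 48.0%, and no pair of libraries differed in that share by Fisher exact tests (smallest adjusted p = 0.102).

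**Figure D2:**
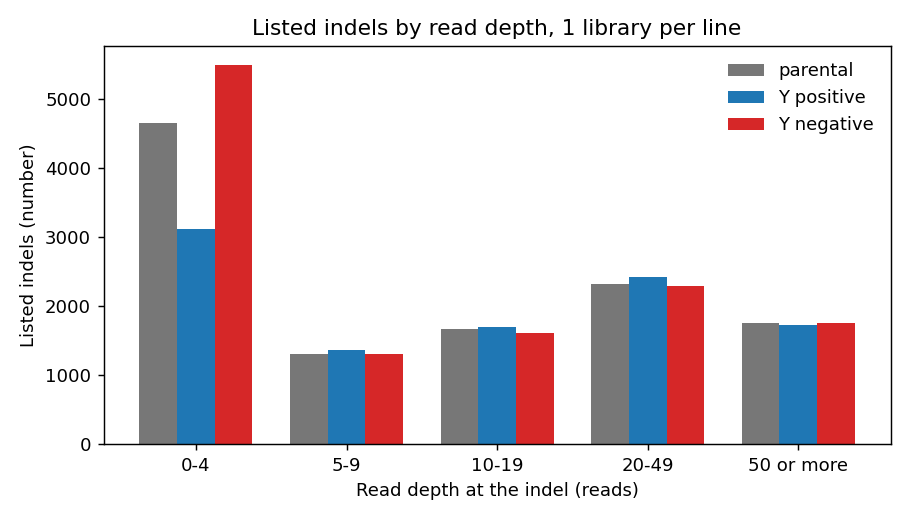
Number of listed indels per library in 5 classes of read depth, 1 bar per library. The libraries differ most in the class of 0 to 4 reads, with 4653 parental, 3125 Y positive and 5499 Y negative indels, and lie close together at 20 to 49 reads, with 2324, 2429 and 2291.

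Indels predicted to change a protein were few in every library. Coding entries numbered 188 in parental, 202 in Y positive and 186 in Y negative, of which 132, 147 and 138 were frameshifts and 55, 53 and 47 were in frame. As a share of all entries, coding indels were 1.49% in Y negative and 1.95% in Y positive (Fisher exact test, adjusted p = 0.0183). At depth 20 or more the shares were 4.03% and 3.92%, in the opposite order and not different (Fisher exact p = 0.821). At depth 20 or more, frameshifts were 76.7% of 163 coding indels in Y negative and 78.5% of 163 in Y positive, a difference that did not pass the Fisher exact test (adjusted p = 0.857). Frameshifts listed in all 3 libraries at that depth in each numbered 96, and 28 of them were homozygous in all 3.

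A further comparison asked how far the derived lines kept the parental indels. All 3 libraries listed 4245 of the 23347 indels found in any, 18.2% (95% interval 17.7 to 18.7). The Jaccard index was 0.310 for Y positive and parental, 0.287 for Y negative and Y positive, and 0.267 for Y negative and parental. Over indels with at least 20 reads in at least 1 library, it was 0.629, 0.603 and 0.611. Private entries, listed in 1 library alone, numbered 6518 in Y negative, 5639 in parental and 4274 in Y positive.

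Sharing depended on genotype and depth. Of homozygous indels at depth 20 or more, 95.8% of parental (95% interval 94.5 to 96.9), 96.0% of Y positive and 95.9% of Y negative entries were in all 3 lists. Of heterozygous indels at that depth the shares were 57.6%, 56.2% and 55.7%. Of homozygous entries below 5 reads, 5.08%, 7.59% and 4.81% were in all 3 lists. Private heterozygous indels at depth 20 or more had median allele fractions of 0.286, 0.312 and 0.277, against 0.471, 0.479 and 0.475 for those in all 3 lists.

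Coding indels at depth 20 or more were mostly shared. In parental 82.5% of 154 (95% interval 75.5 to 88.1), in Y positive 78.5% of 163 and in Y negative 79.8% of 163 were in all 3 lists. Private coding indels over all depths numbered 27 in parental, 32 in Y positive and 26 in Y negative. At depth 20 or more they numbered 12, 12 and 17, another order, with 17 of 163 against 12 of 163 not different between Y negative and Y positive (Fisher exact p = 0.437). With an allele fraction of at least 0.25 as well, 2 parental, 4 Y positive and 5 Y negative private coding indels were listed.

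The Y positive ones were 4 single-base A deletions that shift the frame. That at 7:111338113 lay in transcript ENSMUST00000060440 and was carried by 88 of 219 reads (0.402, 95% interval 0.336 to 0.470), and that at 11:85635526 by 25 of 54 reads. In Y negative, a 6-base insertion at 16:32752958 that keeps the frame, in transcript ENSMUST00000096106, was carried by 47 of 68 reads (0.691, 0.567 to 0.798). A 2-base frameshift deletion of AA at 7:51200694 to 51200695 was carried by 24 of 38 reads. Slippage or alignment error, weighed below for single-base A or T indels, was not tested for these private indels. By transcript, 27 groups of overlapping transcripts held a private coding entry in Y positive and 24 in Y negative, 5 and 2 of them more than 1. The most in any group was 2 entries. Groups with 2 included ENSMUST00000029520 and ENSMUST00000031562 in Y positive, and ENSMUST00000035484 and ENSMUST00000062451 in Y negative. A private entry shows that the other lists lack the indel, not that their reads do.

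Allele fractions were close between the libraries where an indel was listed in both. Between Y negative and Y positive, 21 of 2645 sites differed (0.794%, 95% interval 0.492 to 1.21), 7 with a higher and 14 with a lower allele fraction in Y negative. Unadjusted p was under 0.05 at 164 sites. Y positive differed from parental at 24 of 2745 sites, with 20 higher and 4 lower in Y positive. Y negative differed from parental at 8 of 2651 sites, with 6 higher and 2 lower in Y negative. Among the sites that differed, 0 were coding in each comparison, out of 137, 135 and 130 coding sites tested. The rates over all sites tested were 0.794%, 0.874% and 0.302%. At such rates few or no coding sites would differ, so the count of 0 does not set coding indels apart.

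An intronic A deletion at 16:29261083 was carried by 160 of 160 reads in Y positive, 73 of 179 in Y negative and 59 of 118 in parental (adjusted p = 4.48e-36 for Y negative against Y positive, Fisher exact test). An intronic T deletion at X:153789796 was carried by 47 of 50, 7 of 31 and 8 of 35 reads in the same order (Fisher exact test, adjusted p = 2.01e-08). An intronic T deletion at 4:146886442 was carried by 96 of 178, 38 of 200 and 72 of 199 reads (Fisher exact test, adjusted p = 1.63e-09). An intronic G deletion at 11:62887027 was higher in Y negative, at 43 of 71 reads against 9 of 38 in Y positive and 12 of 51 in parental (Fisher exact test, adjusted p = 0.0349). Of the 21 sites, 15 were single-base A or T indels, 71.4% against 48.8% of all sites tested. The other 6 were not single-base A or T indels. When only the 1353 sites of that other kind were tested, 3 of the 6 passed the threshold, the adjustment alone having changed.

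**Figure D3:**
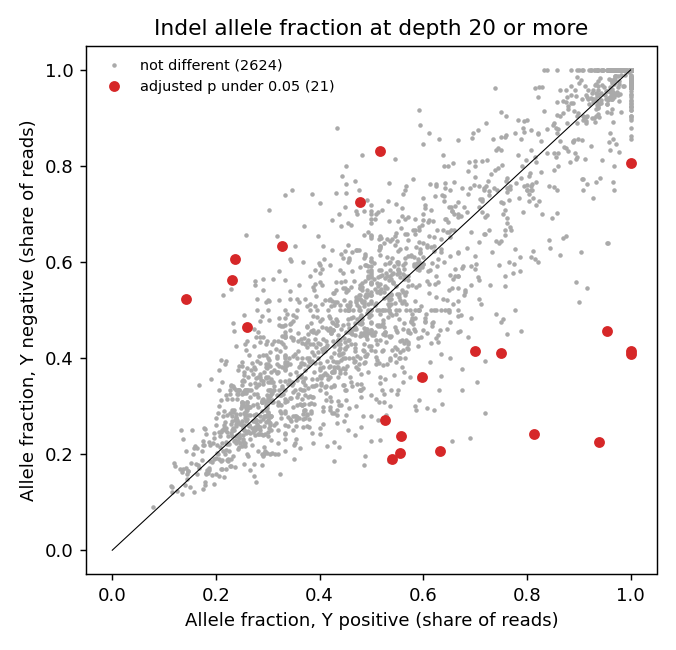
Allele fraction of each indel in Y negative against Y positive, at sites with at least 20 reads in both libraries, with the diagonal of equal values. The 21 sites that differed are in red, 14 of them below the diagonal and 7 above it.

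Median allele fraction per chromosome, at indels listed in all 3 libraries with at least 20 reads in the library measured, was also close between libraries. The median range over the 3 libraries was 0.0201. The widest was 0.140, on X, where the medians were 0.927 in parental, 0.940 in Y positive and 0.800 in Y negative over 48, 49 and 41 sites. On chromosome 13 the medians were 0.568, 0.690 and 0.700 over 91, 93 and 92 sites, with parental apart. The sites differ between libraries in both cases. At the sites with at least 20 reads in all 3 libraries, the medians were 0.879, 0.940 and 0.800 over 35 sites on X and 0.568, 0.634 and 0.611 over 83 sites on chromosome 13. These medians were not tested.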

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

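The tests of single-base A or T indels, of change in 1 line alone, of the whole of X and of sequence shared by X and Y were chosen after the result was seen. The simulation of equal allele fractions and the comparison with other runs of sites were written before their results, but the limits of the far end of X were set after its depths were seen.

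A difference between the derived lines drew attention to the 21 sites whose allele fraction differed between Y negative and Y positive. Sampling of reads alone gave at most 1 such site in 100 simulated pairs of libraries with equal allele fractions, which argues against it. Slippage or alignment error at single-base A or T indels may account for part of them. Such indels made up 71.4% of the sites that differed against 48.7% of the others (one-sided Fisher exact p = 0.0305). The remaining 6 of the 21 were of another kind. The sequence around them was not looked up, so slippage or alignment error stays open there too. A change in 1 derived line is a hypothesis that was not separated from the others: 15 of the 18 sites with a parental depth of at least 20 differed from parental in 1 line alone at an unadjusted p of 0.05, and 12 at the adjusted threshold. The line was Y positive at 10 of the 15 and Y negative at 5, and at the adjusted threshold Y positive at 8 and Y negative at 4. The count of sites differing in 1 line alone is largely set by choosing sites where the derived lines differ, since the same count with parental in the place of a derived line was 19 of 23 (one-sided Fisher exact p = 0.642). Some sites, such as X:153789796, entered both counts, so that p does not compare independent sets of sites.

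The lower depth of Y negative than Y positive at the far end of X was weighed in the same way. Scatter of depth between sites stays open: 7 of 3772 runs of 16 neighbouring sites elsewhere, 0.186%, had a median as low. The runs overlapped, each starting 1 site after the last, so the 7 need not be separate places. That share was under the bound of 1 in 100 set in advance, but the bound was wrong for a run whose limits were picked after its depths were seen. The lowest run elsewhere reached -0.64. A difference along the whole of X is not settled by the difference between the rest of X and the far end, 0.53 in log2 with a bootstrap interval of -0.02 to 1.75, while the rest of X itself had a median of -0.04 (-0.18 to 0.03). A candidate explanation is sequence shared by X and Y whose Y copy is lost in Y negative, which the parental to Y positive ratio of -0.56 (-1.29 to -0.18) leaves open, being below 0 as on chromosome Y but almost the same as in Y negative over the 16 indels, while in the first cluster alone parental depth lay between the other libraries at 7 of 9. Y positive held 2.97 times the reads of Y negative in the first cluster and 1.06 times in the second, without intervals. In the first, the site X:166416845 alone held 461 of the 801 Y positive and 168 of the 270 Y negative reads. Losing 1 of 2 copies would give a 2-fold difference, but the copy number of this sequence in each line is not known. The ratios therefore do not decide for or against a lost Y copy.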

How the results depend on the processing

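The exclusion of single-base A or T indels and the depth minimum of 20 for Y entries, depth windows, coding share and private coding indels were added after seeing the data. At depth 20 or more the entries fell to 4086 parental, 4155 Y positive and 4044 Y negative, and by construction private entries fell to 618, 676 and 739, while the Jaccard index was 0.603 for Y negative and Y positive, 0.629 for Y positive and parental and 0.611 for Y negative and parental. Matching on position alone gave 0.312, 0.337 and 0.288. Leaving out single-base A or T indels, which removes their calls by construction, gave 3, 8 and 3 sites of different allele fraction for Y negative against Y positive, Y positive against parental and Y negative against parental. Y entries at depth 20 or more numbered 0 in parental. At that depth the coding share turned, from -0.463 to 0.108 percentage points in Y negative minus Y positive. Windows past the depth limit numbered 0 in each comparison at a limit of 1. At depth 20 or more in every library, where windows left with fewer than 5 indels dropped out, the windows past the limit also numbered 0 in each. Without the lowest 10% of sites by depth they numbered 0 for Y positive against parental and 3 for Y negative against parental, and with mean centring 2 for the latter. The cause was not tested, except that fewer sites enter under a minimum. The other 48 values moved by less than their interval or 1.5 times, and 0 of these changed direction. No filter setting changed a value, as all entries had passed. No paired analysis was possible because each group held 1 library. Not run were the gene list alternatives and the ampliconic Y families, for lack of gene symbols, the removal of known polymorphic sites, as no entry carried an identifier, and substitutions alone. Low depth limits the entries under 5 reads, and the minimum of 20 also leaves out the entries with at least 5 but fewer than 20 reads.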

Other observations

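The windows and the test of strain ancestry were chosen after the homozygous indels were seen, and the test of capture density was written before its result, in place of an earlier comparison with heterozygous indels (5.71% of them in the 20 fullest windows), which homozygosity itself would lower. The indels listed in all 3 libraries with at least 20 reads in each numbered 2299, of which 862 were homozygous and 1331 heterozygous in every library. The homozygous ones were gathered in a few stretches of the genome. The 2 fullest 5 Mb windows lay side by side on chromosome 3, with 61 from 85000001 to 90000000 and 54 from 90000001 to 95000000, where heterozygous indels numbered 1 and 8. Further stretches lay on chromosome 2 (45 from 80000001 to 85000000) and chromosome 11 (43 from 40000001 to 45000000). No homozygous indel was found in 283 of the 444 windows that held at least 1 of the 2299 indels, and many of those windows held few indels of either kind. The 5 chromosomes 3, 2, 11, 8 and 4 held 66.1% of the homozygous and 30.5% of the heterozygous indels.

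The density of captured sequence is argued against as the only source of these stretches: the 20 windows with most indels in a random 0.5 of the homozygous ones held 58.0% of the remaining 431 but 5.28% (95% interval 4.31 to 6.40) of the 1855 indels listed in 1 library alone at depth 20 or more. Of the latter 96.3% were heterozygous, which homozygosity would lower, so a part played by density next to local homozygosity stays open. A possible explanation, offered as a hypothesis, is DNA of another mouse strain or substrain in the ancestry of the line. It could not be tested, because 0 entries carried a variant identifier to match to a strain. No biological explanation tied to the groups was tested, since the stretches were shared by all 3 libraries.

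The parental library listed 1 indel on the mitochondrial genome, at M:16092, carried by 59 of 267 reads (22.1%), and the other libraries listed 0.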
